A study of Homo sapiens with 24 samples.

How the data were processed

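RNA from 2 human pancreatic cancer cell lines, PANC-1 and Capan-1, was measured on 24 Illumina one-colour bead arrays hybridised with biotin-labelled cRNA, 2 arrays for each of 12 groups. Per the labels, cells were treated with DMSO or with 10 uM of an IRAK1/4 inhibitor for 24 h. Other cells were transduced with retroviral hairpins and selected with puromycin (1 ug/mL, 48 h) and, after a second virus carrying scramble or shIRAK4, with geneticin (500 ug/mL, 4 days), in medium with 10% serum. RNA was extracted with Trizol and cleaned on RNeasy columns. The series description assigns the hairpins to PANC-1 only, but hairpin arrays are present for both lines and both were analysed.

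The authors deposited a table of gene-level log2 signal intensity, called non-normalized per the file headers and made with GenomeStudio 2011 per the labels, with 34595 rows. The log2 step preceded deposit, and neither the background step nor the way probes were combined per gene is stated. Beside each signal the authors deposited a detection p-value, which sets the gene against the negative controls of its array, and its steps fit 770 such controls. A second table deposited by the authors holds log2 values that are quantile normalized over the 24 arrays, judged from the values (34588 rows, 34587 of them shared). It served only as an alternative. The design foresaw linear values of single probes, which neither table holds.

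Signals were returned to the linear scale and processed in R 4.3.3 with limma 3.58.1 in the manner of its neqc function: normexp background correction, offset 16, quantile normalization over the 24 arrays and log2. The background mean and SD were inferred from the detection p-values of the 27191 rows that behave as 1 probe. The function's default infers them from all rows, which gave a background mean of 64.4 to 89.6, where the signal at a detection p near one in 2 was 24.3 to 25.1. With 1-probe rows alone the mean was 25.4 to 26.6. The SD inferred with it ran from 9.45 in Capan1 scramble replicate 2 to 45.6 in Panc1 DMSO replicate 1, above the mean on most arrays. This change was made after counts and leading genes under the default had been seen, and the closing section gives the counts both ways. A gene entered a comparison if its detection p was under 0.01 on both arrays of at least 1 compared group. In the 7404 rows of several probes, 7225 of 18100 values over a log2 level of 8 (39.9%) were not detected, against 0 of 94700 in 1-probe rows, so their detection p is unreliable and no bound was computed for them. For other genes absent from 1 side of a comparison, the fold is given as a bound from the detection limit. Arrays carried 10015 to 12090 detected genes.

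One limma model with 12 group means (12 residual degrees of freedom, prior degrees of freedom 3.91, prior SD 0.141) was fitted to all arrays. It gave inhibitor against DMSO and each knockdown against scramble within each line, the difference of the inhibitor and of the shIRAK1+4 effect between lines, and shIRAK1+4 against the sum of the single knockdowns. The moderated t-test was adjusted by Benjamini and Hochberg's method within each comparison, with a threshold of 0.05. The model pools the spread of all groups, although the SD between the 2 arrays of a group ran from 0.11 in DMSO to 0.31 in Capan1 shIRAK1+4. When 1 array was left out, its lone partner was assumed to vary like the other groups. The 24 gene lists, fixed before the data were examined, were tested with camera (inter-gene correlation preset at 0.01), with camera using an estimated correlation and with fry, adjusted over the lists of a comparison. Their members were also counted with p-values adjusted over the list alone. Lists of fewer than 2 tested genes had no list test. Agreement between comparisons was measured by Pearson's r and Spearman's rho across genes and by Fisher's exact test on shared calls, in 1 family of 16. Comparisons that share scramble arrays were set against 50 simulations without an effect.

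The named genes were chosen by a rule fixed before any value was seen. IRAK1 and IRAK4 are named in every comparison. For each line's inhibitor and shIRAK1+4 comparison, the 8 largest rises and 8 largest falls past the threshold with all 4 array-to-array differences of 1 sign are named, with the 3 largest members of each list past camera's threshold. For single knockdowns it is 4 each way, for interactions and additivity 3 each way, and for shared calls 5 per direction. Some genes that the rule names are not reported here, though all tests and counts over genes and lists include them. Gene names are those of the file: 17761 rows carry a current symbol, 3306 match 1 older symbol and 13528 match none, of which 9818 are named LOC and a number and 3270 HS. and a number, and 479 symbols cover 2 or more rows.

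The steps were tested on simulated data with 200 changed genes in 3 runs, on the layout of 2 comparisons. The simulated background had a smaller SD than any inferred from the data, so the rates below may not carry over to the data. With equal spread, 26.9% of 1.5-fold, 83.6% of 2-fold and 99.5% of 4-fold changes were recovered in the layout of the Panc1 inhibitor comparison, and 29.9%, 86.6% and 99.0% in that of Capan1 shIRAK1+4. False calls made up 19.3% and 19.5% of calls, above the 5% aimed for, and 4.68% and 6.28% among genes detected in both groups, since the filter admits background genes that chance lifted in 1 group. With each group's own spread, false calls were 4.28% in the Panc1 layout and 55.7% in the Capan1 layout (35.4% among genes detected in both groups). The calls of Capan1 shIRAK1+4 thus carry a larger false share than the threshold states, and those of other noisy knockdown groups, which were not simulated, may do so too. Of the genes called in the data, those detected in both groups were 603 of 687 with the inhibitor in Panc1, 2858 of 3517 in Capan1, 1285 of 1530 with shIRAK1+4 in Panc1 and 528 of 595 in Capan1. In 20 runs with 1 list shifted 1.5-fold, camera called it 20 times and called other lists 2 times. Genes varied independently in these runs, which left out background correction and normalization. They therefore cannot show how camera fares with correlated genes. In the data, 62 of 71 list calls were lost with an estimated correlation.

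Alternatives planned beforehand changed the background correction, scaling, detection filter, adjustment, prior, replicate block, deposited table, fold minimum, list test or the arrays used, or fitted each line alone. Median scaling set each array by the median over all rows, of which 28.9% to 34.9% were detected. That median lies near background, so differences of intensity among detected genes stayed in. The shifted medians of all genes given with it below show this. Alternatives added after the data were seen changed the pooled spread (arm alone, line and arm alone, array weights per group), the rows behind the background and the filter for rows of several probes. A mean of probes and a slide block were planned and not run, as the table holds 1 value per gene and the headers name no slide. No sample was excluded, and no column of values lacked a sample.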

Results

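Gene expression was measured on 24 one-colour Illumina bead arrays from 2 established human pancreatic cancer cell lines, PANC-1 (Panc1) and Capan-1 (Capan1). Each line had 6 groups of 2 arrays. A pair of groups received either the vehicle DMSO or an inhibitor of the kinases IRAK1 and IRAK4, given at 10 uM for 24 h. The other 4 groups carried retroviral short hairpin RNAs: a scrambled control (scramble), a hairpin against IRAK1 (shIRAK1), a hairpin against IRAK4 (shIRAK4), or both (shIRAK1+4). IRAK1 and IRAK4 relay signals from IL-1 and Toll-like receptors towards NF-kB. Between 10015 and 12090 genes per array had a detection p under 0.01, and the log2 level at which detection began lay between 5.52 and 5.72. All levels and fold changes are on the log2 scale, fold changes are given ± SE from limma (negative for falls) with 2 arrays per group, and their precision is limited by the number of arrays. The labels do not say whether the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. For every named gene that rose or fell, all 4 array-to-array differences had the sign of the fold change. A value marked as fitted has an uncertain size, because a group did not detect the gene on both arrays or, for additivity, because the sum lay under the detection limit.

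The lines differed in their epithelial markers. Of 32 such markers, 27 were detected on all 12 Capan1 arrays, with a median level of 9.99, against 8 on all 12 Panc1 arrays, with a median of 5.64. Of 23 mesenchymal markers, 8 were detected on every array of either line. Most markers of other cell types were detected on none of a line's arrays: 9 of 13 fibroblast and stellate cell markers, 11 of 15 immune cell markers and 8 of 9 endothelial cell markers in Panc1, and 11, 9 and 6 of them in Capan1.

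The level of the targeted kinases was examined first. In Panc1, IRAK1 lay at 11.41 ± 0.16 (SD, n = 2) in scramble arrays, 8.94 ± 0.89 in shIRAK1 and 8.50 ± 0.20 in shIRAK1+4, a change of -2.47 ± 0.29 (limma adjusted p = 5.77e-05) and -2.91 ± 0.29 (adjusted p = 1.17e-05). With shIRAK4 alone it lay at 11.74 ± 0.31, a difference of 0.34 ± 0.29 (adjusted p = 0.485). In Capan1, IRAK1 lay at 10.44 ± 0.04 in scramble arrays and fell with shIRAK1+4 (-1.60 ± 0.29, limma adjusted p = 0.00483), a call lost without Capan1 scramble replicate 1 (adjusted p = 0.0578) and with a spread from the same line and arm alone (adjusted p = 0.115). Its limma difference was -1.19 ± 0.29 with shIRAK1 (adjusted p = 0.0532), past the threshold under several alternatives and with an adjusted p of 0.0163 under array weights per group, and -0.85 ± 0.29 with shIRAK4 (adjusted p = 0.0874, past the threshold under median scaling at 0.0386, with a background from all rows at 0.0161 and also with a replicate block). IRAK4 lay close to the detection limit in every group, between 5.26 and 6.18. It was detected on neither scramble array of either line and on none of the shIRAK4 and shIRAK1+4 arrays, so the arrays do not show whether the hairpin lowered it against scramble. In Panc1 it was detected on both shIRAK1 arrays (5.91 and 6.01) and on neither shIRAK1+4 array (5.23 and 5.29). IRAK4 thus lay lower there with both hairpins than with shIRAK1 alone, near the detection limit and without a test. In Panc1 shIRAK1 it was at least 1.2-fold above scramble (0.48 ± 0.13 as fitted, limma adjusted p = 0.0315), a call lost when any 1 of the 4 arrays was left out (adjusted p = 0.0721 to 0.178). It was also lost under median scaling (limma adjusted p = 0.196), each line alone (0.0584), no detection filter (0.0601), array weights (0.0719) and a fold of at least 1.5, and with a background from all rows, where the difference was 0.05 (0.0547).

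**Figure D1:**
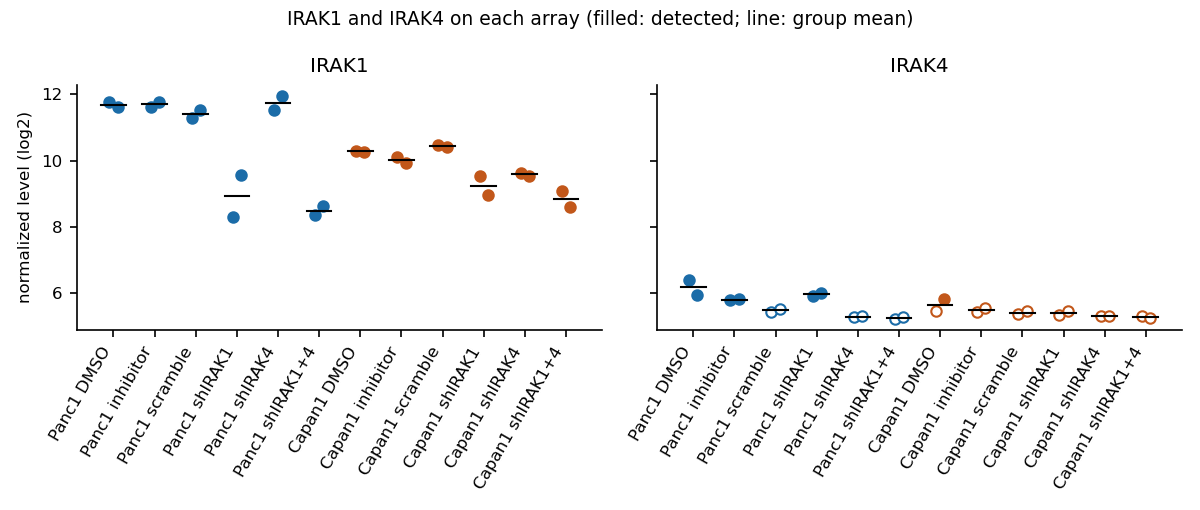
Log2 level of IRAK1 and IRAK4 on each of the 24 arrays, by group, with filled points for detected values and a line at the group mean. Panc1 IRAK1 lay at 11.41 in scramble arrays and at 8.94 and 8.50 with shIRAK1 and shIRAK1+4, while IRAK4 stayed between 5.26 and 6.18 in all group means.

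The inhibitor was compared with DMSO in each line to ask which genes the compound changed. In Panc1, genes of the ATF4 and amino acid response rose as a group: 16 of 21 tested members rose and 0 fell (19 and 0 adjusted over the list alone). Their median fold change was 0.98. TRIB3, a pseudokinase induced under amino acid and endoplasmic reticulum stress, rose by 2.73 ± 0.30 (limma adjusted p = 5.81e-05). NUPR1, a stress-induced nuclear protein, rose by 2.17 ± 0.31, ASNS, asparagine synthetase, by 1.54 ± 0.29, and GPT2, a mitochondrial alanine aminotransferase, by 1.99 ± 0.27. Of 15 NRF2 targets, which act against oxidative stress, 4 rose and 0 fell (5 and 0 adjusted over the list alone). They included HMOX1, heme oxygenase 1 (1.92 ± 0.28), SRXN1, which reduces oxidised peroxiredoxins (0.79 ± 0.18), and SLC7A11, a cystine transporter (0.79 ± 0.10). Among the other large rises were HSPA6, a heat-inducible chaperone (1.78 ± 0.13 as fitted), OKL38 (now OSGIN1, induced by oxidative stress; 1.75 ± 0.18), P8 (2.05 ± 0.34) and LOC440900 (1.88 ± 0.19). P8 is an older name of NUPR1, S100A8 and NUPR2, so its row may be a second one of NUPR1.

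The largest falls in Panc1 with the inhibitor were CRISPLD2 (-1.83 ± 0.31, limma adjusted p = 0.00219), LIPG, endothelial lipase (-1.75 ± 0.33), ZNF467 (-1.65 ± 0.29), LXN, a carboxypeptidase inhibitor (-1.65 ± 0.36), and TNFRSF1B, a TNF receptor (-1.54 ± 0.42). TMPRSS2, a membrane serine protease (-1.50 ± 0.36), RASD2 (-1.45 ± 0.40) and EDN1, the precursor of endothelin (-1.33 ± 0.26), fell as well. Of 27 NF-kB and inflammatory targets, 4 fell and 1 rose (8 and 1 adjusted over the list alone). TNFAIP2 (-1.16 ± 0.30) and BCL3 (-0.95 ± 0.25) fell, and the cytokine LIF rose (0.64 ± 0.17). Of 15 epithelial markers, 2 fell and 0 rose (4 and 0 adjusted over the list alone), namely keratin 19 (KRT19, -1.21 ± 0.18) and plakoglobin (JUP, -1.10 ± 0.19). Of 22 extracellular matrix and TGF-beta targets, the collagen genes COL5A2 (-0.79 ± 0.13) and COL1A1 (at least 1.47-fold lower) fell and CTGF (now CCN2) rose (1.39 ± 0.39), or 6 falls and 2 rises adjusted over the list alone.

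In all, 687 of 10469 genes passed the threshold in Panc1 with the inhibitor, 379 higher and 308 lower, and camera called 5 of 23 lists. The ATF4 list had an adjusted p of 2.05e-22, and adjusted p = 0.0205 with an estimated correlation. The NF-kB, epithelial, NRF2 and matrix lists had camera adjusted p of 0.000159, 0.00102, 0.00224 and 0.0191, and each was lost at adjusted p = 0.491 with an estimated correlation. Median scaling, which took the median of all genes to 0.05, left 37 genes (34 higher, 3 lower) and none of the falls named here, leaving out any 1 of the 4 arrays left 217 to 263 genes, and a spread estimated from the inhibitor arm alone gave 2278. Of the 37 named genes, 8 kept their side of the threshold under every alternative: TRIB3, NUPR1, P8 (possibly NUPR1 again), LOC440900, HSPA6, OKL38, SLC7A11 and STC2. The targets did not pass, IRAK1 at 0.01 ± 0.29 and IRAK4 at -0.37 ± 0.13.

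In Capan1, NF-kB and inflammatory targets fell with the inhibitor (camera adjusted p = 1.62e-11), a list call lost at adjusted p = 0.147 with an estimated correlation, as were the 10 other calls of this comparison. Of 35 tested members, 23 fell and 2 rose (24 and 2 adjusted over the list alone), with a median fold change of -1.39. Among the largest falls were the chemokines CCL20 (-5.16 ± 0.81) and CCL2 (-4.97 ± 0.37 as fitted) and lymphotoxin beta (LTB, -5.42 ± 0.51 as fitted, limma adjusted p = 1.50e-06). LTB lay at 5.43 and 5.35 on the inhibitor arrays and was detected on neither, so the size of its fall is not known. IL32, an inflammatory cytokine (-4.67 ± 0.31 as fitted), and UBD, a ubiquitin-like protein induced by TNF and interferon gamma (-4.28 ± 0.25), fell too. IGFBP1, an insulin-like growth factor binding protein (-4.29 ± 0.26), C13ORF15 (now RGCC, at least 15.3-fold lower) and the cadherin CDH17 (at least 20.8-fold lower) were also among the 8 largest.

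Genes of DNA replication and the G1/S transition fell in Capan1 with the inhibitor, 26 of 34 (27 adjusted over the list alone) with 0 rising. RRM2, a subunit of ribonucleotide reductase (-1.93 ± 0.25), POLE2, of DNA polymerase epsilon (-1.83 ± 0.19), and MCM6, of the replicative helicase (-1.54 ± 0.16), were the largest. By contrast, 11 of 31 mitosis genes rose and 1 fell (11 and 1 adjusted over the list alone), among them NEK2 (1.11 ± 0.21), KIF20A (1.06 ± 0.18) and cyclin B2 (CCNB2, 1.03 ± 0.13). Cholesterol synthesis and uptake fell in 12 of 23 members (12 adjusted over the list alone), including SC4MOL (now MSMO1, -1.77 ± 0.17 as fitted) and squalene epoxidase (SQLE, -1.55 ± 0.20). Matrix and TGF-beta targets fell in 8 of 18 members (9 adjusted over the list alone), including matrilysin (MMP7, -3.89 ± 0.20) and CYR61 (now CCN1, at least 9.22-fold lower). Immediate early genes fell in 9 and rose in 1 of 21 members (10 and 1 adjusted over the list alone), with JUN at -2.89 ± 0.27, FOSL1 at -2.18 ± 0.49 as fitted and IER3 at -1.83 ± 0.13. Genes that report MAPK pathway output fell in 6 of 15 (7 adjusted over the list alone), among them the EGF receptor ligand HBEGF (-1.76 ± 0.41). The type I interferon list had 6 falls and 2 rises among 24 members, the same counts adjusted over the list alone, with IFI6 at -2.21 ± 0.70, ISG15 at -1.57 ± 0.39 and ISG20 at -1.32 ± 0.33.

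Other groups rose in Capan1 with the inhibitor. Hypoxia and glycolysis genes rose in 13 of 21 (16 adjusted over the list alone) with none falling, among them PFKFB4, a regulator of glycolysis (3.30 ± 0.68), NDRG1 (3.02 ± 0.68) and aldolase C (ALDOC, 2.30 ± 0.65). The ATF4 list rose in 12 and fell in 1 of 18 (12 and 2 adjusted over the list alone), with PHGDH, the entry enzyme of serine synthesis (3.17 ± 0.28), DDIT4, an inhibitor of mTORC1 (3.14 ± 0.43), and ASNS (1.73 ± 0.29). Of 5 aryl hydrocarbon receptor targets, 3 rose, the same count adjusted over the list alone: the xenobiotic-metabolising enzymes CYP1A1 (2.76 ± 0.14 as fitted), ALDH3A1 (2.30 ± 0.22) and NQO1 (1.08 ± 0.27 as fitted). The largest single rises were keratin 13 (KRT13, at least 22.8-fold higher), LOC100133817 (4.02 ± 0.51), PROM2 (3.93 ± 0.22), DMBT1, a mucin-like epithelial glycoprotein (3.69 ± 0.42 as fitted), CRISPLD2 (3.68 ± 0.31), the GABA receptor subunit GABBR2 (3.64 ± 0.22), PSCA, prostate stem cell antigen (3.58 ± 0.37), and CAPS (3.36 ± 0.25 as fitted). In DMSO, inhibitor and scramble arrays, KRT13 lay at 5.31, 10.09 and 10.40, PROM2 at 5.76, 9.69 and 9.76, and CRISPLD2 at 7.67, 11.35 and 9.68. These 3 genes were thus also above DMSO in scramble arrays, without the inhibitor.

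In Capan1, 3517 of 10871 genes passed, 1790 higher and 1727 lower, and camera called 11 of 23 lists. Besides NF-kB, its adjusted p was 3.01e-11 for DNA replication, 3.67e-06 for hypoxia, 2.41e-05 for ATF4, 4.04e-05 for cholesterol, 0.000291 for mitosis, 0.000436 for matrix, 0.000507 for aryl hydrocarbon receptor targets, 0.00116 for immediate early genes, 0.00536 for MAPK output and 0.0328 for interferon. None of these held, at adjusted p = 0.186 to 0.598 with an estimated correlation, while fry, which asks only whether a list's genes moved one way on balance, called 17 lists. Median scaling, which took the median of all genes to 0.36, gave 1974 genes (1675 higher, 299 lower) and the same list directions, leaving out Capan1 DMSO replicate 1 or 2 or inhibitor replicate 1 left 2183, 2175 and 2240, and a spread estimated from the inhibitor arm alone gave 5399. Of the 53 named genes, 35 kept their side of the threshold under every alternative, and IFI6, ALDOC and CDH17 were among those that did not. IRAK1 did not pass (-0.25 ± 0.29).

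The difference between the inhibitor's effects in the lines was tested as an interaction, Panc1 minus Capan1. Among the most positive terms were those of CCL20 (4.32 ± 1.14, limma adjusted p = 0.0179), LTB (4.76 ± 0.73 as fitted, adjusted p = 0.000497) and IGFBP1 (4.28 ± 0.37 as fitted), all of which fell in Capan1. Among the most negative were those of CRISPLD2 (-5.51 ± 0.44), which fell in Panc1 and rose in Capan1, and of KRT13 (-4.79 ± 0.68 as fitted) and PROM2 (-3.96 ± 0.31 as fitted). LTB was not detected with the inhibitor in either line, KRT13 in Capan1 DMSO, and IGFBP1, KRT13 and PROM2 in Panc1 with DMSO or inhibitor, so the sizes and ranks of these terms rest on background values. ASNS, which rose in both lines, differed by -0.19 ± 0.41 (adjusted p = 0.797). Interaction terms of 1929 of 12168 genes passed, 951 positive and 978 negative. Median scaling took the median of all genes to -0.24 and left 281 (106 and 175) without CCL20, leaving out 1 array left 1065 to 1338, and a spread from the inhibitor arm alone gave 4177.

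**Figure D2:**
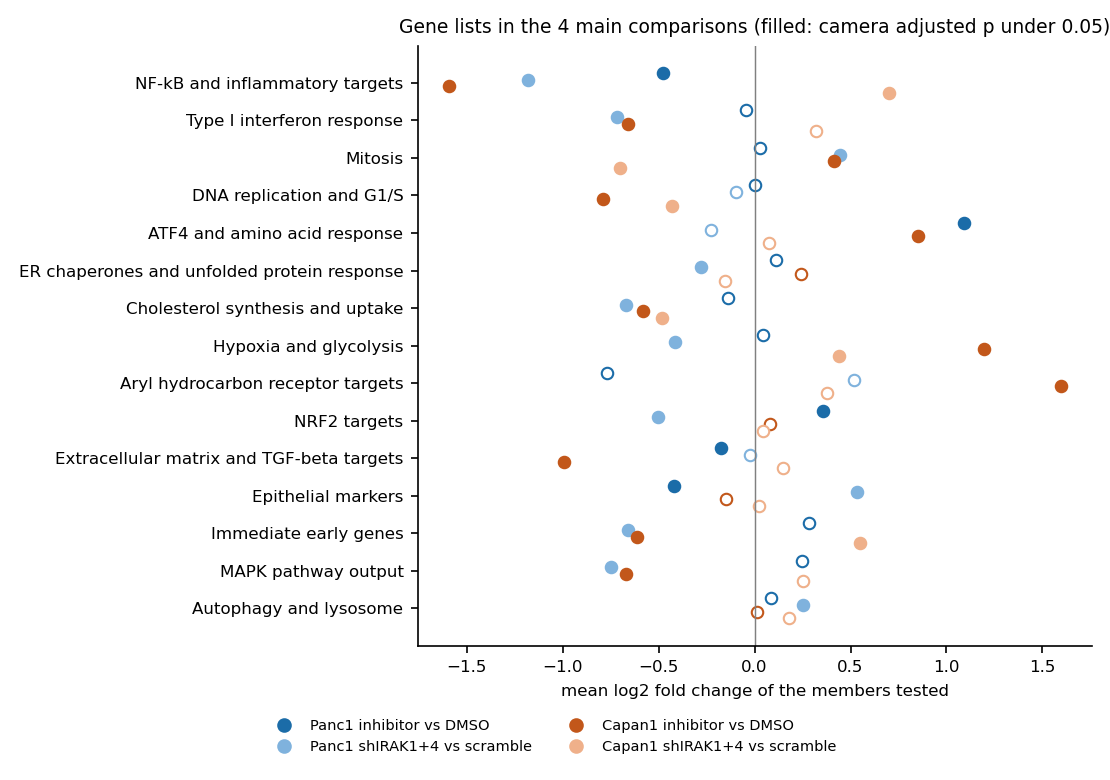
Mean log2 fold change of 15 gene lists in the 4 main comparisons, with filled points for lists past camera's adjusted p of 0.05. NF-kB targets had a median fold change of -1.39 with the inhibitor in Capan1 and -1.08 with shIRAK1+4 in Panc1, against 0.58 with shIRAK1+4 in Capan1.

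Knockdown of both kinases was compared with scramble as the genetic counterpart of the inhibitor. In Panc1, NF-kB and inflammatory targets fell with shIRAK1+4 in 12 of 20 members (15 adjusted over the list alone) and rose in 0, a list call lost at adjusted p = 0.0623 with an estimated correlation. They included interleukin 8 (IL8, now CXCL8, -3.09 ± 0.50, limma adjusted p = 0.000749), CCL2 (-2.52 ± 0.37) and IL32 (-1.55 ± 0.31). Cholesterol synthesis and uptake fell in 13 of 21 members (15 falls and 1 rise adjusted over the list alone), among them the synthase HMGCS1 (-2.15 ± 0.19), INSIG1, a sterol-sensing regulator (-1.27 ± 0.22), and MVD, mevalonate decarboxylase (-1.06 ± 0.15). Immediate early genes fell in 7 of 19 (8 adjusted over the list alone), with EGR1 at -3.35 ± 0.37, FOSB at -1.88 ± 0.19 and JUND at -0.84 ± 0.16. MAPK output genes fell in 7 of 14 (8 adjusted over the list alone), with HBEGF at -2.50 ± 0.41, the feedback inhibitor SPRY4 at -1.30 ± 0.23 and the phosphatase DUSP6 at -1.28 ± 0.26 as fitted. NRF2 targets fell in 5 of 15 (6 adjusted over the list alone), with HMOX1 at -1.84 ± 0.28, malic enzyme ME1 at -1.08 ± 0.24 and GCLM, of glutathione synthesis, at -0.83 ± 0.20. Mitosis genes rose in 14 of 30 (17 adjusted over the list alone), with the kinase AURKB at 1.13 ± 0.16, CDCA8 at 0.87 ± 0.23 and DLGAP5 at 0.85 ± 0.17. In Panc1 DMSO, scramble and shIRAK1+4 arrays, the median level of list members was 7.999, 8.88 and 8.25 for cholesterol, 6.69, 8.40 and 6.94 for immediate early genes, 9.35, 8.72 and 9.32 for mitosis and 6.78, 6.58 and 5.60 for NF-kB.

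Epithelial markers rose in 5 of 14 in Panc1 shIRAK1+4, the same count adjusted over the list alone. EPCAM, an epithelial adhesion molecule, rose by 2.32 ± 0.16 in its own row and by 2.32 ± 0.15 as fitted in the row under its older name TACSTD1. E-cadherin (CDH1) was at least 2.98-fold higher and JUP rose by 0.90 ± 0.19. Autophagy and lysosome genes rose in 4 and fell in 1 of 22 (5 and 1 adjusted over the list alone), with rises of GABARAPL1 (1.63 ± 0.25) and LAMP1 (0.88 ± 0.12). Of 19 chaperones of the endoplasmic reticulum, 2 fell (4 adjusted over the list alone), ARMET (now MANF, -1.38 ± 0.17) and HERPUD1 (-0.67 ± 0.18). Of 20 hypoxia genes, 2 fell (6 adjusted over the list alone), ALDOC (-2.32 ± 0.65) and BNIP3 (-1.39 ± 0.24). The interferon list held 1 fall, IFITM1 (-2.05 ± 0.64), and 1 rise, MX2 (0.45 ± 0.13), among 25 members, with 0 of either adjusted over the list alone. The largest single rises were the chemokine receptor CCR7 (at least 12.2-fold higher), COL5A2 (at least 10.9-fold), dermokine (DMKN, 2.99 ± 0.13), the proteoglycan SPOCK1 (2.65 ± 0.40), LOC649970 (2.50 ± 0.35) and the imprinted transcript H19 (2.48 ± 0.67). Besides IRAK1 and genes already named, the largest falls were BCAT1, a branched-chain aminotransferase (-3.01 ± 0.09 as fitted), the desaturase SCD (-2.95 ± 0.44) and the chemokine CX3CL1 (-2.55 ± 0.54).

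Of 10369 genes tested with shIRAK1+4 in Panc1, 1530 passed, 847 higher and 683 lower, and camera called 11 of 23 lists. The cholesterol list (camera adjusted p = 1.92e-10) held, at adjusted p = 0.0335 with an estimated correlation. The NF-kB list (adjusted p = 9.53e-11) and immediate early genes (adjusted p = 2.68e-06) were both lost, at adjusted p = 0.0623 with an estimated correlation. Mitosis, MAPK output and NRF2 (adjusted p of 3.39e-07, 8.10e-06 and 0.000144) were lost at adjusted p = 0.201 with an estimated correlation. Interferon, epithelial, endoplasmic reticulum, autophagy and hypoxia lists (adjusted p of 0.00151, 0.00774, 0.00906, 0.0219 and 0.0227) were lost, at adjusted p = 0.343 to 0.609 with an estimated correlation. Median scaling, which took the median of all genes to 0.12, left 167 genes (114 higher, 53 lower) and turned no list, leaving out any 1 of the 4 arrays left 632 to 801, and array weights per group gave 3251. Of the 50 named genes, 22 kept their side of the threshold under every alternative, among them CCR7, COL5A2, EPCAM, EGR1, CCL2, HMGCS1, SCD and IRAK1, while IFITM1, H19, CDH1, ALDOC and MX2 did not.

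In Capan1, mitosis genes fell with shIRAK1+4 in 20 of 30 members (27 adjusted over the list alone) and rose in 0. The kinase NEK2 (-1.12 ± 0.21), the kinesin KIF20A (-0.97 ± 0.18) and cyclin B1 (CCNB1, -0.91 ± 0.20) fell most. The median level of mitosis genes was 8.64 in scramble arrays, 8.09 with shIRAK1+4 and 7.97 in DMSO arrays. DNA replication genes fell in 5 of 33 (19 adjusted over the list alone), with MCM2 at -0.91 ± 0.21, MCM3 at -0.87 ± 0.12 and the histone mRNA binding protein SLBP at -0.52 ± 0.14. Cholesterol genes fell in 10 of 23 (15 falls and 1 rise adjusted over the list alone), with INSIG1 at -1.87 ± 0.22 as fitted (limma adjusted p = 0.000191) and the isomerase IDI1 at -1.11 ± 0.15. NF-kB and inflammatory targets rose in 9 and fell in 1 of 31 (13 and 1 adjusted over the list alone), with CCL20 at 3.35 ± 0.81, IL32 at 2.20 ± 0.31 and CCL2 at 1.65 ± 0.37 as fitted. The CCL20 levels of the 2 shIRAK1+4 arrays were 7.33 and 11.08. Immediate early genes rose in 5 of 20 (9 adjusted over the list alone), with IER3 at 1.24 ± 0.13, JUN at 1.16 ± 0.27 and KLF6 at 0.92 ± 0.18. Under median scaling the list's median turned from 0.40 to -0.15, but relative to the median of all genes it stayed positive (0.32). ANGPTL4, a lipase inhibitor, rose by 1.57 ± 0.38 in the hypoxia list, 1 of 18 by either adjustment, adjusted over the list alone included. That list's median turned from 0.28 to -0.18 under median scaling, but stayed positive relative to the median of all genes (0.29).

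Among single genes in Capan1 shIRAK1+4, the trypsinogens PRSS1 (2.66 ± 0.30) and PRSS2 (2.27 ± 0.21), IGFBP1 (2.55 ± 0.26), the elastase inhibitor PI3 (2.32 ± 0.54), LOC100134294 (2.14 ± 0.13) and the ribosomal RN5S9 (1.89 ± 0.35) had the largest rises. KRT13 (-2.92 ± 0.48), tyrosine hydroxylase (TH, -2.78 ± 0.12 as fitted), the protocadherin PCDH20 (at least 5.66-fold lower), the transcription cofactor VGLL1 (-1.98 ± 0.26), LYPD2 (-1.94 ± 0.48), PSCA (-1.86 ± 0.37) and SCD (-1.81 ± 0.44) had the largest falls. In DMSO, scramble and shIRAK1+4 arrays, IGFBP1 lay at 10.44, 6.68 and 9.23, and KRT13 at 5.31, 10.40 and 7.48. Both thus moved from the scramble towards the DMSO level. Of 10663 genes tested, 595 passed, 243 higher and 352 lower, and camera called 6 of 23 lists. Mitosis (camera adjusted p = 3.87e-21), cholesterol (adjusted p = 4.11e-08) and immediate early genes (adjusted p = 2.55e-07) held, at adjusted p = 0.0381, 0.0412 and 0.0412 with an estimated correlation. NF-kB (adjusted p = 1.28e-09), DNA replication (adjusted p = 5.01e-10) and hypoxia (adjusted p = 0.0259) were lost, at adjusted p = 0.0513, 0.247 and 0.635 with an estimated correlation. Median scaling, which took the median of all genes to -0.47, gave 911 genes (23 higher, 888 lower), while leaving out Capan1 scramble replicate 1 or 2 left 123 or 215, and leaving out shIRAK1+4 replicate 1 gave 1487. A spread taken from the shRNA arrays of Capan1 alone left 4 genes, and 3 of the 36 named genes, LOC100134294, TH and PCDH20, kept their side of the threshold under every alternative.

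The effect of shIRAK1+4 in the lines was compared by the interaction, Panc1 minus Capan1. CCR7 (4.09 ± 0.11 as fitted, limma adjusted p = 8.83e-13), COL5A2 (3.79 ± 0.19 as fitted) and KRT13 (adjusted p = 0.0113) were among the most positive terms, and CCL20 (-5.83 ± 1.14 as fitted, adjusted p = 0.00469), EGR1 (-4.52 ± 0.53) and IL8 (-4.51 ± 0.71) among the most negative. CCR7 and COL5A2 were not detected in Panc1 scramble arrays or in Capan1, nor KRT13 in Panc1, so the sizes and ranks of these terms rest on background values. CCL2 and IL32 fell in Panc1 and rose in Capan1, with differences of -4.17 (as fitted) and -3.75. KIF20A fell in Capan1 and had a fold change of 0.74 in Panc1, a difference of 1.70 (adjusted p = 0.000713). The fall of IRAK1 did not differ by this test (-1.31 ± 0.42, limma adjusted p = 0.0548), but it passed under some alternatives, with an adjusted p of 0.0377 under array weights per group and 0.0285 with a background from all rows. Terms of 1243 of 12019 genes passed, 725 positive and 518 negative. Median scaling took the median of all genes to 0.53 and gave 740 (702 and 38), and leaving out 1 array gave 640 without Capan1 scramble replicate 1 up to 1769 without Capan1 shIRAK1+4 replicate 1. CCR7, COL5A2, IL8 and EGR1 passed under every alternative, CCL20 and KRT13 did not.

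**Figure D3:**
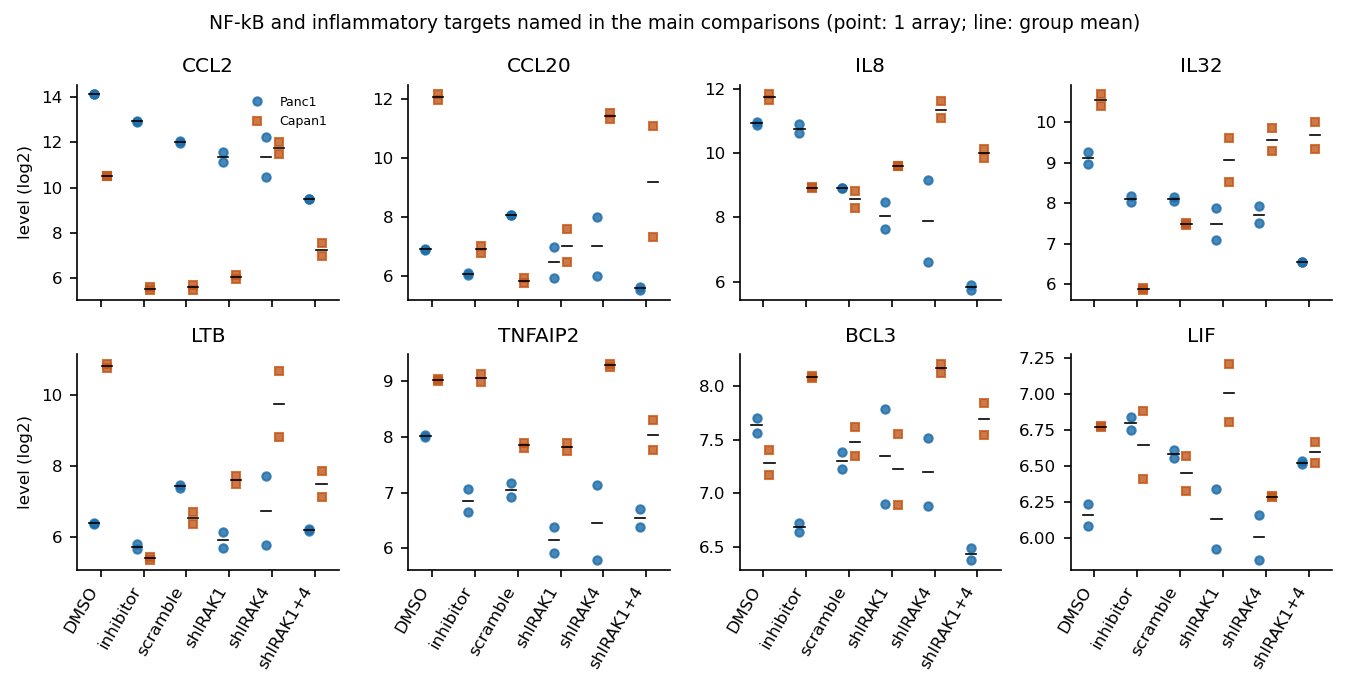
Log2 level of 8 NF-kB targets on each array, by group. CCL2 lay at 10.52 in Capan1 DMSO, 5.55 with the inhibitor, 5.61 in scramble and 11.77 with shIRAK4, while in Panc1 it lay at 12.02 in scramble and 9.50 with shIRAK1+4.

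The single hairpins were set against the same scramble arrays. In Panc1, cholesterol genes fell in 17 of 21 with shIRAK1 (17 adjusted over the list alone) and 14 of 22 with shIRAK4 (18 falls and 1 rise adjusted over the list alone). Camera's adjusted p was 3.06e-23 and 3.82e-12, and both held, at adjusted p = 0.000972 and 0.026 with an estimated correlation. SCD fell (-3.71 ± 0.44 and -3.26 ± 0.44), as did EGR1 (-3.51 ± 0.37 and -3.05 ± 0.37) and the interferon lambda gene IL29 (now IFNL1, -4.06 ± 0.42 as fitted and -2.99 ± 0.42). The median level of cholesterol genes was 8.88 in scramble arrays, 7.85 with shIRAK1, 8.31 with shIRAK4 and 7.999 in DMSO arrays, and EGR1 and IL29 lay at 10.30 and 10.26 in scramble arrays and at 6.16 and 5.36 in DMSO arrays. With shIRAK1, IL28A (now IFNL2) fell (-3.75 ± 0.33 as fitted), and TXNIP, a thioredoxin-binding protein (4.28 ± 0.57), PLIN2, a lipid droplet protein (3.74 ± 0.39), C10ORF116 (now ADIRF, 2.77 ± 0.22) and H19 (2.67 ± 0.67) rose most. With shIRAK4, BCAT1 fell (-3.07 ± 0.09 as fitted), and SLC4A11, a membrane transporter (3.38 ± 0.32 as fitted), MT1M, a metallothionein (at least 5.92-fold higher), the carboxylesterase CES1 (2.79 ± 0.23 as fitted) and SOX21, a transcription factor (2.77 ± 0.23), rose most. NF-kB targets fell in 7 of 22 with shIRAK1 (11 adjusted over the list alone; camera adjusted p = 6.69e-07) and 5 of 20 with shIRAK4 (8 adjusted over the list alone; camera adjusted p = 0.000786). Both were lost, at adjusted p = 0.155 and 0.315 with an estimated correlation, and the shIRAK4 call also without shIRAK4 replicate 2 (adjusted p = 0.495). Mitosis genes rose in 10 of 30 with shIRAK1 (19 adjusted over the list alone; camera adjusted p = 3.51e-10, and adjusted p = 0.13 with an estimated correlation).

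With shIRAK1 in Panc1, 1060 of 10092 genes passed (557 higher, 503 lower), and with shIRAK4, 1356 of 10201 (723 higher, 633 lower). Camera called 11 and 13 lists, of which only the cholesterol list held with an estimated correlation. For shIRAK1 the calls included p53 targets (1 of 15 fell, 0 adjusted over the list alone; adjusted p = 0.0329, and adjusted p = 0.319 with an estimated correlation) and apoptosis regulators (4 fell and 1 rose of 21, the same adjusted over the list alone; adjusted p = 0.0329, and adjusted p = 0.13 with an estimated correlation). The median of the apoptosis list, -0.25, turned to 0.01 under median scaling, but stayed negative relative to the median of all genes (-0.23). For shIRAK4 they included fibroblast and stellate cell markers, of which 1 of 2 tested rose, also adjusted over the list alone (camera adjusted p = 0.0343, and adjusted p = 0.315 with an estimated correlation). Median scaling took the medians of all genes to 0.24 and 0.16 and left 157 (113 higher, 44 lower) and 196 genes (160 higher, 36 lower), and leaving out scramble replicate 1 or 2 left 482 or 456 with shIRAK1 and 602 or 649 with shIRAK4. Apart from H19 and IRAK4 with shIRAK1, the named genes kept their side of the threshold under every alternative.

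In Capan1, NF-kB and inflammatory targets rose with shIRAK4 in 25 of 35 members (29 adjusted over the list alone), with 0 falling (camera adjusted p = 3.01e-29, and adjusted p = 0.00547 with an estimated correlation). CCL2 rose by 6.15 ± 0.37 as fitted (limma adjusted p = 3.21e-08), CCL20 by 5.58 ± 0.81, PIGR, the transporter of polymeric antibodies, by 4.52 ± 0.58 and the class II antigen HLA-DRA by 4.07 ± 0.41. The scramble arrays were themselves low, with 24 of 34 NF-kB targets under DMSO. In DMSO, scramble and shIRAK4 arrays, CCL20 lay at 12.08, 5.86 and 11.44, and CCL2 at 10.52, 5.61 and 11.77. Against DMSO, CCL20 was thus not raised, while CCL2 lay higher. Of 5 immune cell markers tested, 3 rose, the same adjusted over the list alone (camera adjusted p = 0.000218, and adjusted p = 0.152 with an estimated correlation). KRT13 (-3.68 ± 0.48), TH (-2.91 ± 0.12 as fitted, not detected with either single hairpin), PCDH20 (-2.49 ± 0.24 as fitted) and TMEM154 (-2.47 ± 0.09) were among the largest falls. KRT13 lay at 10.40 in scramble and 6.73 in shIRAK4 arrays, but at 5.31 and undetected in DMSO arrays. With shIRAK1, the cystatin CST1 (2.86 ± 0.63), LOC100134294 (2.59 ± 0.13), interleukin 1 alpha (IL1A, at least 5.32-fold higher) and PRSS1 (2.55 ± 0.30) rose most, and osteopontin (SPP1, -3.93 ± 0.64), TH (-2.81 ± 0.12 as fitted), PCDH20 (at least 5.69-fold lower) and KRT13 (-2.53 ± 0.48) were among the largest falls. NF-kB targets rose in 6 and fell in 1 of 30 with shIRAK1 (8 and 1 adjusted over the list alone; camera adjusted p = 2.04e-06, and adjusted p = 0.287 with an estimated correlation). The list's median of 0.34 fell just under 0 under median scaling, but stayed positive relative to the median of all genes (0.39). Cholesterol genes fell in 5 of 23 with shIRAK1 (12 falls and 1 rise adjusted over the list alone; camera adjusted p = 4.56e-10, and adjusted p = 0.046 with an estimated correlation) and in 7 of 23 with shIRAK4 (13 falls and 2 rises adjusted over the list alone; camera adjusted p = 1.45e-05, and adjusted p = 0.152 with an estimated correlation).

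With shIRAK1 in Capan1, 179 of 10696 genes passed (98 higher, 81 lower), and with shIRAK4, 935 of 10974 (498 higher, 437 lower), and camera called 6 and 8 lists. Only cholesterol with shIRAK1 and NF-kB with shIRAK4 held with an estimated correlation. MAPK output with shIRAK1 (camera adjusted p = 0.000159) and autophagy with shIRAK4 (adjusted p = 0.0142) were among those lost, at adjusted p = 0.39 and 0.345 with an estimated correlation. Median scaling took the medians of all genes to -0.39 and -0.36 and gave 65 (10 higher, 55 lower) and 445 genes (95 higher, 350 lower), turning the medians of MAPK output with shIRAK1 (0.28 to -0.06) and of autophagy with shIRAK4 (0.21 to -0.15). Relative to the median of all genes these 2 stayed positive (0.33 and 0.21). Leaving out scramble replicate 1 or 2 left 58 or 76 with shIRAK1 and 351 or 384 with shIRAK4, leaving out shIRAK1 replicate 1 left 103, and a spread taken from the Capan1 shRNA arrays alone left 4 and 49. LOC100134294, PCDH20 and TH with shIRAK1, and CCL2, HLA-DRA, TMEM154, PCDH20 and TH with shIRAK4, kept their side of the threshold under every alternative.

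Because the 3 knockdowns of a line share their scramble arrays, their fold changes correlate with no effect at all. In Panc1, Pearson's r across genes, which are not independent replicates, was 0.785 between shIRAK1 and shIRAK4, against 0.50 simulated without an effect, with a covariance of 0.118 against 0.0175. A total of 302 genes were higher and 309 lower in both, where 35.8 and 32.2 would be shared by independent lists. In Capan1 the same r was 0.416, against 0.499 simulated, with a covariance of 0.0510 against 0.0182, and 43 genes were higher and 37 lower in both, against 3.97 and 3.38. For shIRAK4 and shIRAK1+4 r was 0.779 in Panc1 (0.499 simulated) and 0.615 in Capan1 (0.4997 simulated), and for shIRAK1 and shIRAK1+4 it was 0.652 (0.498 simulated) and 0.519 (0.4997 simulated). For the last pair in Capan1 the covariance was 0.0521 against 0.0183, with 38 genes higher and 44 lower in both, against 2.03 and 2.75. The simulated r was near 0.50 for every pair. Scramble arrays, however, lay closer together (SD 0.13 in Panc1 and 0.14 in Capan1) than those of most knockdown groups (0.21 to 0.31). The simulated r therefore cannot decide whether an r of 0.416 or 0.519 exceeds what shared controls give. The 2 scramble arrays were not split between the knockdowns, so part of the excess may come from the shared controls.

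Departure from additivity was tested as shIRAK1+4 minus the sum of the single knockdowns. In Panc1, the interferon lambda genes IL29 (5.33 ± 0.59 as fitted, limma adjusted p = 3.79e-05) and IL28A (4.76 ± 0.46 as fitted), which fell with each single hairpin or with shIRAK1, and CCR7 (4.05 ± 0.11 as fitted, detected with shIRAK1+4 alone) lay above the sum. For IL29 and IL28A the sum is a level of 3.21 and 3.51, under the detection limit and under every value on the arrays, so part of these departures was fixed in advance. TXNIP (-5.88 ± 0.81), C10ORF116 (-3.88 ± 0.31) and PLIN2 (-3.80 ± 0.56), which rose with shIRAK1, lay below it. In Capan1, SPP1 (3.65 ± 0.90 as fitted), KRT13 (3.29 ± 0.68 as fitted) and SPRR3, a cornified envelope protein (2.97 ± 0.31 as fitted), lay above the sum, and CCL2 (-4.97 ± 0.52 as fitted), the defensin DEFB1 (-3.84 ± 0.68) and serum amyloid SAA1 (-3.57 ± 0.37) below it. The sums of SPP1, KRT13 and SPRR3 are 4.69, 4.19 and 4.46, again under every value on the arrays. The contrast also holds the scramble level. In scramble and DMSO arrays, IL29 lay at 10.26 and 5.36 and PLIN2 at 7.06 and 9.40 in Panc1. In Capan1, KRT13 lay at 10.40 and 5.31 and CCL2 at 5.61 and 10.52, but SPRR3 at 7.41 and 6.89. Where all 3 knockdowns return a gene from such a scramble level, the term departs with the same sign. This was not separated from an interaction of the hairpins. Of the terms above the sum, 96 in Panc1 and 30 in Capan1 had a sum under the detection limit. The terms of 816 of 10974 genes passed in Panc1 (383 above, 433 below) and 273 of 11511 in Capan1 (172 of them below), and IRAK1 passed in neither (-0.78 ± 0.42 and 0.44 ± 0.42). Median scaling took the medians of all genes to -0.25 and 0.25 and left 108 (18 above, 90 below) and 26 (12 above, 14 below), and leaving out 1 array gave 402 without Panc1 shIRAK1+4 replicate 2 up to 1186 without Panc1 shIRAK4 replicate 2, and 113 without Capan1 scramble replicate 2 up to 712 without Capan1 shIRAK1+4 replicate 2. A spread from the shRNA arrays of Capan1 alone left 8 terms there, and of the Capan1 genes named here CCL2 alone passed under every alternative.

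The inhibitor and the double knockdown, which share no arrays, were then set against each other within each line. In Panc1, STC2, a secreted glycoprotein, rose by 1.26 ± 0.15 with the inhibitor and by 1.09 ± 0.15 with shIRAK1+4, TMEM187 by 0.97 and 0.79, HS.355933 by 0.77 and 0.73, TMEM86B by 0.94 and 0.68, and HES4, a Notch-related repressor, by 0.64 and 0.96. EDN1 (-1.33 and -1.41), CD83 (-1.06 and -1.26), nestin (NES, -0.95 and -1.71), BCL3 (-0.95 and -0.87) and BMP5 (-0.92 and -0.73) fell with both. HMOX1 and other genes ran the other way: 64 genes rose with the inhibitor and fell with shIRAK1+4, where 23.5 would be shared by independent lists (Fisher's exact test, adjusted p = 3.17e-13), and 54 did the reverse, against 23.5 (adjusted p = 1.54e-08). Shared rises (Fisher's exact test) numbered 26, against 28.8 (adjusted p = 0.723), and shared falls 26, against 19.2 (adjusted p = 0.134). Pearson's r across 9627 genes, which are not independent replicates, was -0.108 (Spearman's rho -0.106).

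In Capan1, ANGPTL4 rose by 1.20 (as fitted) with the inhibitor and 1.57 with shIRAK1+4, TBC1D3G by 0.65 and 0.65, RNU1G2 by 0.60 and 0.60, RBCK1 by 0.58 and 0.69, and LOC440348 by 0.57 and 0.60. Caveolin 1 (CAV1, -2.39 and -1.61), MCM2 (-0.96 and -0.91), IDI1 (-0.88 and -1.11), ACAT2 (-1.42 and -0.86, both as fitted) and monoamine oxidase A (MAOA, -0.80 and -0.89) fell with both. Opposite changes were more frequent: 148 genes rose with the inhibitor and fell with shIRAK1+4, against 56.0 for independent lists (Fisher's exact test, adjusted p = 3.01e-32), and 146 did the reverse, against 38.0 (adjusted p = 2.86e-57). Shared rises (Fisher's exact test) numbered 11, against 38.7 (adjusted p = 8.92e-08), and shared falls 36, against 55.0 (adjusted p = 0.00547). Across 10031 genes r was -0.381 (rho -0.246), and it was -0.211 without shIRAK1+4 replicate 1. Between the lines, by Fisher's exact test, the inhibitor raised 137 genes in both, against 49.9 (adjusted p = 8.84e-32), and lowered 67, against 38.7 (adjusted p = 6.34e-06), with r of 0.154. Opposite changes with the inhibitor numbered 36 higher in Panc1 and lower in Capan1, against 49.996 (Fisher's exact test, adjusted p = 0.0407), and 36 the reverse, against 38.7 (adjusted p = 0.723). shIRAK1+4 raised 19 in both lines, against 13.2 (adjusted p = 0.134), and lowered 25, against 17.2 (adjusted p = 0.0752), with r of -0.0979. By Fisher's exact test its opposite changes passed, 44 higher in Panc1 and lower in Capan1, against 21.4 (adjusted p = 6.34e-06), and 23 the reverse, against 10.6 (adjusted p = 0.000981). These p-values were adjusted over a family of 16 overlaps. Fisher's exact test counts genes as independent, which they are not, so the p-values of both lines may overstate the evidence.

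**Figure D4:**
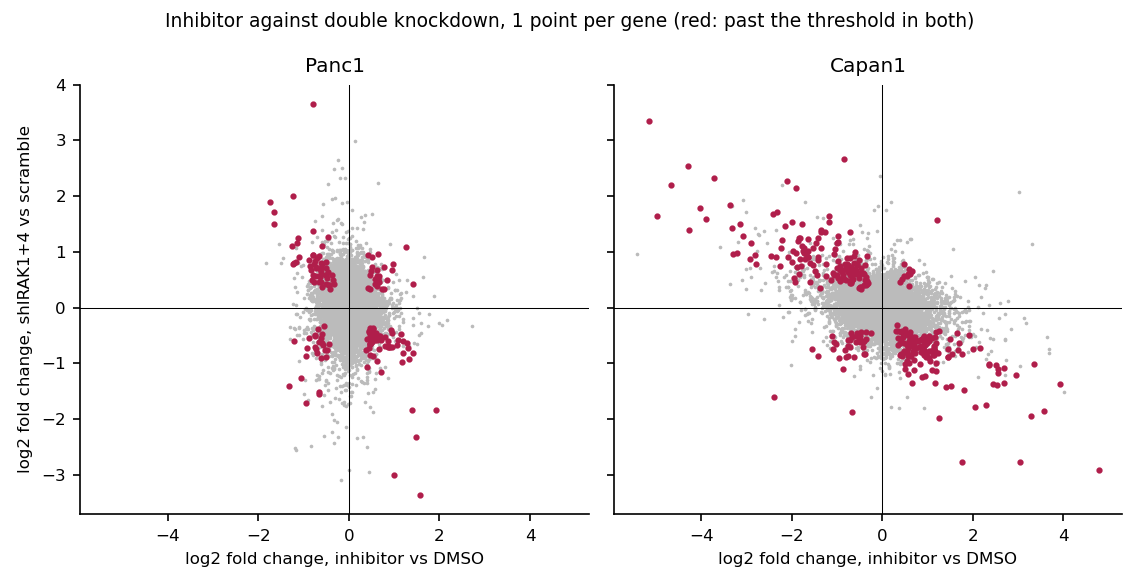
Log2 fold change of each gene with the inhibitor (x axis) and with shIRAK1+4 (y axis) in each line, in red where both passed the threshold. Pearson's r was -0.108 in Panc1 and -0.381 in Capan1.

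Some of the fixed lists were called by camera in none of the 8 treatment comparisons. IL-1 and Toll-like receptor signalling components had 4 falls among 19 members with the inhibitor in Capan1 (adjusted p = 0.0727) and 3 among 13, IRAK1 included, with shIRAK1+4 in Panc1 (adjusted p = 0.261, median 0.06 but mean -0.30). Genes of gemcitabine metabolism and drug efflux had 4 falls among 16 with the inhibitor in Capan1 (adjusted p = 0.101) and 3 rises among 17 with shIRAK1+4 in Panc1 (adjusted p = 0.233). These counts were the same adjusted over the list alone, except for 4 rises in the last. Mesenchymal markers had 2 rises and 5 falls among 10 with the inhibitor in Capan1, also adjusted over the list alone (adjusted p = 0.117). Of 1 endothelial marker tested with shIRAK1+4 in Panc1, 1 rose, and a single gene gives no list test. Reference genes had 2 rises and 3 falls among 15 with the inhibitor in Capan1, also adjusted over the list alone (adjusted p = 0.958, median -0.01). In every list that camera called, the median, the mean and the test had the same sign.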

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

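The results here are named genes whose response differed between the cell lines, with limma's interaction test of the difference past an adjusted p of 0.05. Most were named for a large change within a line, which favours such a difference, so their number does not speak for all genes. Over all genes, 1929 of 12168 passed with the inhibitor and 1243 of 12019 with shIRAK1+4. Values are differences of log2 fold changes, Panc1 minus Capan1, and not of levels. A positive difference can rest on a fall in Capan1 alone, as for TH with shIRAK1+4 (-0.01 in Panc1, -2.78 in Capan1). Where a group did not detect the gene on both arrays, the size of the difference rests on background values. The explanation by the state of the control groups was predicted before its test was run, and the other explanations and their tests were chosen after the results were seen.

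With the inhibitor, 61 named genes differed, and 38 of the differences were positive. Only 8 passed the threshold in both lines, 5 of them with opposite signs. NF-kB targets were LTB (4.76), CCL20 (4.32), CCL2 (3.78), IL32 (3.67), IER3 (1.69), LIF (0.77) and BCL3 (-1.75). Matrix genes were CYR61 (4.09), MMP7 (3.50), CTGF (2.72) and COL5A2 (-0.97). Immediate early and MAPK genes were JUN (3.45), FOSL1 (2.73) and HBEGF (2.16). DNA replication genes were POLE2 (1.83), MCM6 (1.59), RRM2 (1.36) and MCM2 (1.18), and mitosis genes KIF20A (-1.34), CCNB2 (-1.19) and NEK2 (-1.16). Cholesterol genes were SC4MOL (1.79), SQLE (1.26), ACAT2 (0.93) and IDI1 (0.88). ATF4 and NRF2 genes were TRIB3 (2.39), NUPR1 (2.18), HMOX1 (1.66), STC2 (1.32), SRXN1 (0.83), SLC7A11 (0.62) and PHGDH (-1.69). Hypoxia and aryl hydrocarbon receptor genes were PFKFB4 (-3.69), NDRG1 (-3.09), CYP1A1 (-2.74) and ALDH3A1 (-2.19). Other positive differences were those of IGFBP1 (4.28), UBD (3.83), C13ORF15 (3.70), CAV1 (2.13), P8 (2.05), LOC440900 (1.81), HSPA6 (1.81), HES4 (1.41), OKL38 (1.26), EDN1 (1.25), MAOA (0.87) and TMEM86B (0.69). Other negative differences were those of CRISPLD2 (-5.51), KRT13 (-4.79), PROM2 (-3.96), LOC100133817 (-3.89), GABBR2 (-3.85), DMBT1 (-3.71), PSCA (-3.61), CAPS (-3.42), RASD2 (-2.77), ZNF467 (-2.36), LXN (-2.05), BMP5 (-1.01) and TBC1D3G (-0.78).

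With shIRAK1+4, 57 named genes differed, and 25 of the differences were positive. Only 8 passed in both lines, 7 of them with opposite signs. Among NF-kB targets were CCL20 (-5.83), IL8 (-4.51), CCL2 (-4.17) and IL32 (-3.75), and among immediate early genes EGR1 (-4.52), FOSB (-2.64), JUN (-1.93), IER3 (-1.85) and JUND (-0.79). MAPK output genes were HBEGF (-4.00), DUSP6 (-2.03) and SPRY4 (-1.70). NRF2 and hypoxia genes were HMOX1 (-2.01), ME1 (-1.43), ANGPTL4 (-2.61) and BNIP3 (-1.38). Mitosis and replication genes were KIF20A (1.70), DLGAP5 (1.59), NEK2 (1.39), CDCA8 (1.33), AURKB (1.32), CCNB1 (0.94) and MCM3 (0.96). Cholesterol, epithelial, matrix, lysosome, ATF4 and chaperone genes were HMGCS1 (-1.43), EPCAM (2.34), COL5A2 (3.79), LAMP1 (0.88), STC2 (1.05) and ARMET (-0.87). Further positive differences were those of CCR7 (4.09), LOC649970 (2.83), TH (2.76), DMKN (2.70), PCDH20 (2.65), TACSTD1 (2.35), CAV1 (2.26), PSCA (2.09), SPOCK1 (1.92), VGLL1 (1.92), HES4 (1.10), MAOA (0.90) and TMEM86B (0.72), with KRT13 at 3.0003. Further negative differences were those of BCAT1 (-3.01), CX3CL1 (-2.82), PRSS1 (-2.62), RN5S9 (-2.58), IGFBP1 (-2.47), PRSS2 (-2.34), LOC100134294 (-2.10), NES (-2.07), EDN1 (-1.85), CD83 (-1.78), RBCK1 (-1.11), RNU1G2 (-1.09), LOC440348 (-0.87) and BMP5 (-0.74).

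In Capan1, CCL20, IL32, KRT13 and many other genes moved opposite ways with the inhibitor and with shIRAK1+4, with r of -0.381 across genes. A difference between the control groups could give this, and with the controls exchanged r was 0.0521 (SD over single arrays 0.176), the loss of the opposition that was predicted. The same exchange took Panc1 from -0.108 to -0.466. Exchanging the controls puts their difference into the inhibitor and knockdown contrasts with opposite signs, which by itself lowers r. In Panc1 scramble and DMSO arrays differed in 2682 of 10359 genes. The Panc1 value therefore cannot decide whether the state of the controls explains the opposition in that line. Normalization does not account for the opposition in Capan1, since r stayed at -0.360 or further from 0 under 5 normalizations. The biological alternative, that loss of the kinases and their inhibition act differently, was not separated from the state of the controls, because no array carries both treatments.

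The 2 arrays of most knockdown groups lay further apart (SD 0.21 to 0.31) than those of other groups. A swap of labels between Panc1 shIRAK1 and shIRAK4 could do this, but the lowest IRAK1 level with shIRAK4 lay 1.96 above the highest with shIRAK1. A swap in Capan1 was not excluded, since IRAK1 levels overlap there between shIRAK1 (8.96 and 9.54) and shIRAK1+4 (8.59 and 9.09). Noise independent from gene to gene would leave a partner difference unrelated to the difference between the line's other knockdown groups. The median absolute r between them was 0.357 over 5 groups, with signed values from -0.39 to 0.51, which argues against noise of that kind alone. Technical variation that moves many genes together would also correlate, so it was not excluded. No biological explanation was tested, since the labels do not say how the arrays of a group differ.

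NF-kB targets rose in Capan1 shIRAK1+4 against scramble, with a median of 0.58. A low level in the scramble arrays could produce this. Against DMSO the same members had a median of -0.84 ± 0.14 (error over genes), with 27 of 31 below DMSO, and scramble lay below DMSO in 28 of 31, with a median of -1.26 ± 0.28. This is consistent with a rise from a lowered control level, while a biological effect of the hairpins, which the design gives, was not excluded by it.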

How the results depend on the processing

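Counts are genes past the threshold unless lists are named. Of 243 named genes and comparisons, 111 kept their side of the threshold under every setting run, and 5 values reversed. Signal over background limits dim genes such as IRAK4, and 2 arrays per group limit the spread. Spread by arm, by line and arm, array weights, background from all rows and several-probe rows by level were chosen after the data were seen. A mean of probes and a slide block were not run. Unless said otherwise, the cause was not tested. Median scaling set the arrays by a level near background, so changes under it may come from the scaling itself.

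Median scaling gave 37 with the inhibitor in Panc1, 1974 in Capan1, 281 for their difference, 157, 196 and 167 in Panc1 and 65, 445 and 911 in Capan1 with shIRAK1, shIRAK4 and shIRAK1+4, 740 for the line difference, and 108 and 26 for additivity, with 10 lists in Capan1 shIRAK1+4. IRAK1 reversed there, to 0.11 with the inhibitor in Capan1 and to -0.0891 for the line difference. No background correction left 178 and no detection filter 175 Capan1 additivity terms. Each line alone gave 46, 336 and 147 in the Capan1 knockdowns and 72 for additivity. The authors' values gave 365 with the inhibitor in Panc1, 96, 615 and 361 in the Capan1 knockdowns, and 527 and 107 for additivity. A fold of at least 1.5 gave, by its construction, 438 and 2210 with the inhibitor and 649, 785 and 936 in the Panc1 knockdowns.

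Camera with an estimated correlation called 1 and 0 lists with the inhibitor, 1, 1 and 1 in the Panc1 and 1, 1 and 3 in the Capan1 knockdowns, and fry 2 and 17 with the inhibitor and 1 in Capan1 shIRAK1. Spread by arm gave 2278, 5399 and 4177 for the inhibitor, 513, 695 and 844 in the Panc1 and 63, 418 and 184 in the Capan1 knockdowns, 500 for the line difference, and 316 and 78 for additivity. Spread by line and arm gave 2064 with the inhibitor in Panc1, 527, 762 and 899, then 4, 49 and 4, and 283 and 8. Array weights gave 2350, 5448 and 4300 for the inhibitor, 3251 in Panc1 shIRAK1+4, 336 and 241 in Capan1 shIRAK1 and shIRAK1+4, and 121 for Capan1 additivity. A background from all rows gave 3 lists with the inhibitor in Panc1 and an agreement of -0.144 there. Its counts, 880, 2977 and 1832 for the inhibitor, 1049, 1373 and 1527 in the Panc1 and 197, 774 and 533 in the Capan1 knockdowns, 1202 for the line difference, and 834 and 239 for additivity, all stayed within 1.5 times, and 44 of the 243 named values lost the threshold and 3 gained it.

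Leaving out 1 array gave 217 to 263 with the inhibitor in Panc1, 2175 to 2393 in Capan1 and 1065 to 1338 for the difference. In Panc1 it gave 456 to 858 with shIRAK1, 602 to 1242 with shIRAK4 and 632 to 801 with shIRAK1+4, and in Capan1 58 to 184, 351 to 1002 and 123 to 1487. The line difference had 640 to 1769 terms, and additivity 402 to 1186 and 113 to 712. Lists ran from 5 to 10 in Capan1 shIRAK1 and 7 to 11 in shIRAK1+4, and the Capan1 agreement from -0.468 to -0.211. IRAK4 ran from -0.44 without Panc1 DMSO replicate 2 to 0.0249 without replicate 1 for the inhibitor's line difference, and IRAK1 from -0.0675 without inhibitor replicate 2 (-0.0665 without DMSO replicate 2) to 0.0928 without inhibitor replicate 1 with the inhibitor in Panc1. The Type I interferon response list ran from -1.65 without shIRAK1 replicate 1 to 0.13 without replicate 2 in Panc1 shIRAK1, and from -1.38 without shIRAK4 replicate 1 to 0.19 without replicate 2 in Panc1 shIRAK4.

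Array numbers paired the groups in part at most. Differences between the 2 arrays of a group correlated between groups at 0.193 (Capan1) and 0.0406 (Panc1) in the inhibitor arms. In the hairpin arms the range was -0.141 to 0.276 in Capan1 and 0.0173 to 0.481 in Panc1. The highest was between Panc1 shIRAK1 and shIRAK4, so a factor shared by array number in some knockdown groups was not excluded. A replicate block gave 667, 3571 and 1921 for the inhibitor, 1052, 1322 and 1583 in the Panc1 and 139, 886 and 567 in the Capan1 knockdowns, 1222 for the line difference, and 755 and 202 for additivity, and limma passed IRAK1 in Capan1 shIRAK1 (0.0177) and shIRAK4 (0.0333) and for the line difference (0.0207). A detection p under 0.05, adjustment over all kept genes, a trended robust prior and several-probe rows by level moved no count over 1.5 times.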

Other observations

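Scramble and DMSO arrays of the same line were compared outside the planned comparisons, a choice made after the results were seen. They differ in virus, drug selection and vehicle at once. In Panc1, scramble arrays held more of the interferon lambda genes IL28A (at least 16.2-fold, limma adjusted p = 4.95e-07) and IL29, neither detected with DMSO, which belong to antiviral signalling, and of EGR1 (4.14 ± 0.37) and ALDOC (4.06 ± 0.65). They held less LIPG, detected on 1 of 2 scramble arrays, the peptidase ANPEP (-3.40 ± 0.20), the chemokine CXCL1 (-3.29 ± 0.59) and COL5A2 (at least 7.88-fold less). Cholesterol genes were higher in 18 of 21 (19 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.46e-14, and adjusted p = 0.00943 with an estimated correlation). Interferon genes were higher in 7 of 25 (the same adjusted over the list alone; camera adjusted p = 0.00146, and adjusted p = 0.618 with an estimated correlation). Mitosis genes were lower in 18 of 31 (22 adjusted over the list alone; camera adjusted p = 1.57e-07, and adjusted p = 0.242 with an estimated correlation). In all, 2682 of 10359 genes passed, 1246 higher and 1436 lower. Median cholesterol levels were 7.999 with DMSO, 8.88 with scramble and 7.85 to 8.31 with the 3 knockdowns, all nearer to DMSO than to scramble.

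In Capan1, scramble arrays held more KRT13 (at least 28.3-fold, limma adjusted p = 2.55e-06), LYPD2 (4.88 ± 0.48), PROM2 (4.00 ± 0.22) and SPP1, which DMSO arrays did not detect, than DMSO arrays. They held less of the chemokines CCL20 (-6.22 ± 0.81), CXCL1 (-4.06 ± 0.59) and CCL2, detected on 1 of 2 scramble arrays, the cadherin CDH17 (at least 21.6-fold less), LTB (-4.28 ± 0.51) and lysozyme (LYZ, -3.93 ± 0.33). NF-kB targets were lower in 24 of 34 and higher in 1 (26 and 1 adjusted over the list alone; camera adjusted p = 1.74e-20, and adjusted p = 0.0246 with an estimated correlation). Mitosis genes were higher in 20 of 31 (28 adjusted over the list alone; camera adjusted p = 3.01e-15, and adjusted p = 0.0752 with an estimated correlation), and chaperones of the endoplasmic reticulum in 10 of 19 (13 adjusted over the list alone; camera adjusted p = 1.14e-05, and adjusted p = 0.213 with an estimated correlation). In all, 1691 of 10895 genes passed, 861 higher and 830 lower. Median mitosis levels were 7.97 with DMSO, 8.64 with scramble, 8.64 with shIRAK1, 8.24 with shIRAK4 and 8.09 with shIRAK1+4, the last 2 nearer to DMSO than to scramble. The shIRAK1+4 arrays of Capan1 differed from DMSO in 464 genes of 10694.

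Of 24 arrays, 17 had the other array of their group as the closest of all. The others were both arrays of Capan1 shIRAK4, Capan1 shIRAK1+4 and Panc1 shIRAK4 and 1 of Panc1 shIRAK1, each closest to another knockdown group of its line, and no 2 arrays were identical. Except for Capan1 shIRAK4 replicate 1, these arrays were closest to the array of the same replicate number in that other group.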
